A study of Homo sapiens with 6 samples.

How the data were processed

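RNA-seq of 6 human kidney libraries was analysed, 3 of the medullary thick ascending limb (mTAL) and 3 of the proximal tubule (PT), grouped by the cell type and the replicate number that the labels give. Columns were matched to libraries by the segment and number in their headings; the labels also carry another numbering, so replicate numbers may be permuted within a segment. Per the labels' protocols, segments were isolated by repeated collagenase digestion, nuclei were isolated from them, and RNA was extracted and sequenced on a NovaSeq. The rat samples and the chromatin accessibility part of the study were not analysed here. STAR, featureCounts and DESeq2 were used and the genome build was hg38, per the submitters' processing notes; versions, annotation, strand setting and filters are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and near-identical paralogs can share reads.

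The deposited signal is a normalized count per gene and library, in which the authors divided each library's counts by 1 size factor. All values were whole multiples of the value of 1 read (100% within a tolerance of 0.01), and the size factors recomputed from the recovered reads by the median-of-ratios method of DESeq2 equalled the deposited ones. A second deposited table holds the authors' mean signal per segment for 4 genes. Of 60649 genes in the table, 37177 had no read in any library; a point was turned into a hyphen in 4926 names, and 40275 names were found in GENCODE 29 on GRCh38, in RefSeq or in a list of gene symbols. XIST, TSIX and Y-linked genes, 446 in all, were left out.

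Recovered reads numbered 15407452, 14265672 and 5562877 in mTAL replicates 1 to 3 and 6420229, 7189962 and 5714831 in PT replicates 1 to 3. Of the detected genes, 4.57, 3.30, 3.23, 3.66, 3.03 and 3.90% had 1 to 3 reads in the same order, and the median reads of a detected gene were 267.5, 229, 130, 88, 112 and 73. A gene with no read in a library is bounded there by 3 reads, for counting error alone.

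Genes with a normalized count of at least 10 in at least 3 of the 6 libraries were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are mTAL minus PT on that scale, which understates the change of genes low in each library. For a gene unread in only some libraries of a segment, the fold change can instead exceed the log2 ratio of the segment means. No replicate block was used, since the labels only number the replicates. The test and its filter, the alternatives unless stated otherwise, the lists and the rule for named genes were chosen before the data were examined. The 28 lists cover proximal transporters, brush border and endocytosis, gluconeogenesis and fructose use, fatty acid oxidation and peroxisome, amino acid and one-carbon metabolism, xenobiotic and steroid metabolism, glycolysis, thick ascending limb transport and identity, proximal and distal transcription factors, oxidative phosphorylation, mitochondrial mRNA, osmotic stress, hypoxia, the renin-angiotensin and natriuretic pathways, monogenic blood pressure genes, injury, immediate-early and heat shock genes, proliferation, and markers of the thin limb, distal convoluted and connecting tubule, collecting duct, podocytes and parietal cells, endothelium, stroma and smooth muscle, immune cells and erythrocytes. With mitochondrial mRNA listed at 0 throughout, 27 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. With an estimated correlation, camera also tests on the residual degrees of freedom, which are few here, and so loses power. Shares of RNA classes were compared by exact permutation with scipy 1.17.1 in Python 3.11.15, and a Wilson interval at 95% was taken for shares of single libraries.

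Named genes are the 8 with the largest log2 fold change in each direction among genes past the threshold with a mean of at least 50 in the higher segment, no overlap between the segments and a symbol, leaving out pseudogenes; the 3 members of each list with the highest mean over the 6 libraries; 11 index genes of the segments; and the genes of the authors' table. Members of a list past the threshold may be named after these. This gave 94 genes, of which 57 passed. Some of these genes are not reported here.

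Alternatives were a pseudocount of 0.5 or 5, no filter on low values, a mean of at least 50, quantile normalization, rescaling to the same total, a replicate block, array weights, leaving out each library in turn, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald) on the recovered reads. Rescaling to the total outside mitochondrial pseudogenes and rRNA genes, and thinning the reads outside them to the smallest library, were chosen after seeing the data, as was camera with an estimated correlation within the alternatives. The model was tested on simulated data drawn from the libraries' means, depths and within-segment dispersion, with 200 genes changed: of 175 changed genes among 11581 that passed the filter, 10.3% were recovered, none at 2-fold or 4-fold, 14.3% at 8-fold and 32.5% at 16-fold, with 4 of 22 calls false and 4.61% of unchanged genes at an unadjusted p below 0.05. Nuclear copies of mitochondrial genes were aligned to their mitochondrial gene with edlib 1.3.9.post1, and plots were drawn with matplotlib 3.10.9.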

Results

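RNA was sequenced from 2 segments of the human kidney tubule, isolated by collagenase digestion. They were the medullary thick ascending limb (mTAL), which reabsorbs salt without water, and the proximal tubule (PT), which reabsorbs most of the filtered glucose, amino acids, phosphate and bicarbonate. Each segment had 3 libraries, and the labels state that RNA was taken from isolated nuclei. The series concerns noncoding variants associated with blood pressure, and the comparison here asks how the transcriptomes of the segments differ. The labels number the replicates without saying that they came from separate donors, so p-values measure the spread between these samples, which may be technical. The deposited values are counts divided by 1 size factor per library, from which whole reads could be recovered. The mTAL libraries held 15407452, 14265672 and 5562877 reads and the PT libraries 6420229, 7189962 and 5714831. Genes with at least 1 read numbered 17304, 16916 and 9971 in mTAL replicates 1, 2 and 3, and 14268, 12201 and 12728 in PT replicates 1, 2 and 3. PCR reads without molecular identifiers are not independent molecules, so intervals and floors given below cover counting error only.

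SLC12A1, UMOD and KCNJ1 of the thick ascending limb were higher in mTAL, and 6 index genes of the proximal tubule were higher in PT. SLC12A1, the apical sodium-potassium-chloride cotransporter, stood at 21269 ± 12367 normalized counts in mTAL and 355 ± 56.6 in PT (SD, n = 3 per segment throughout), a log2 fold change of 5.66 (SE 0.52, limma adjusted p = 0.00261). UMOD, which encodes uromodulin, stood at 74774 ± 55941 against 2008 ± 1057 (log2 4.78, SE 0.90, adjusted p = 0.026), and KCNJ1, the apical potassium channel ROMK, at 2501 ± 1761 against 136 ± 69.9 (log2 4.10, SE 0.58, adjusted p = 0.0113). LRP2, the endocytic receptor megalin, had no read in any mTAL library and 4871 ± 653 normalized counts in PT, at least 2118-fold lower in mTAL (adjusted p = 0.00189), and its partner cubilin, CUBN, fell by 7.19 on the log2 scale from PT to mTAL (SE 0.56, adjusted p = 0.00147). Folds against a segment with no read use a floor of 3 reads per library, averaged over the libraries of that segment. Here and below, such folds are lower bounds for counting error alone. Zeros also stood beside high values within a segment: SPP1 had 1676 and 4900 in mTAL replicates 1 and 2 and 0 in replicate 3. SLC5A2, the glucose cotransporter SGLT2, was at least 384-fold lower in mTAL (adjusted p = 0.0174). Neither it nor LRP2 was tested without a PT library. The phosphate cotransporter gene SLC34A1 had a log2 fold change of -8.38 (SE 1.75, adjusted p = 0.0355), the organic anion transporter gene SLC22A6 -9.11 (SE 1.68, adjusted p = 0.0246) and the transcription factor gene HNF4A -8.66 (SE 1.74, adjusted p = 0.0327). Their means were 24.8, 27.2 and 27.2 in mTAL against 1430, 2427 and 1826 in PT, with no read in some mTAL libraries. Their smallest log2 fold changes among the alternatives were -5.86, -6.47 and -6.05. CLDN16, a tight junction gene of paracellular magnesium transport, stood at 39.0 ± 36.9 in mTAL and 146 ± 61.3 in PT without passing (log2 -3.20, SE 1.93, adjusted p = 0.386). Several calls were lost when 1 library was left out. UMOD missed the threshold without mTAL replicate 1 (adjusted p = 0.0666) or PT replicate 1, 2 or 3 (0.0544, 0.0736 and 0.0962). SLC34A1 missed it without mTAL replicate 1 (adjusted p = 0.0617) or PT replicate 1, 2 or 3 (0.122, 0.146 and 0.155), as did HNF4A (0.0575, 0.104, 0.129 and 0.168), and SLC22A6 missed it without PT replicate 1, 2 or 3 (0.0973, 0.101 and 0.125). By edgeR and DESeq2, SLC34A1 (adjusted p = 0.172 and 0.181), HNF4A (0.151 and 0.125) and SLC22A6 (0.131 and 0.0881) did not pass. With a replicate block, SLC34A1 (0.0622), HNF4A (0.0519) and SLC5A2 (0.0597) did not.

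**Figure D1:**
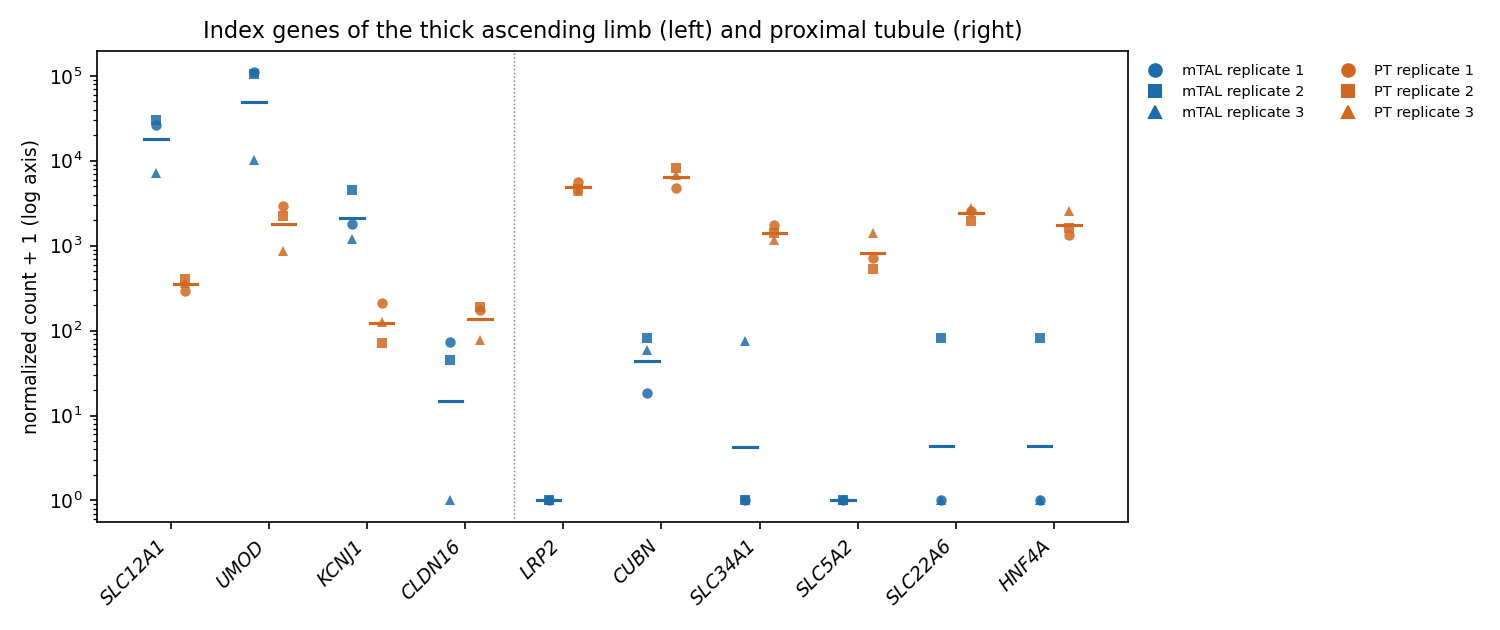
Normalized count plus 1 (log axis) of 10 index genes in each library, with mTAL in blue, PT in orange and a marker shape per replicate; bars are means of log2(value + 1). SLC12A1 lies at 21269 ± 12367 in mTAL against 355 ± 56.6 in PT, LRP2 at 0 in each mTAL library against 4871 ± 653 in PT, and CLDN16 at 39.0 ± 36.9 against 146 ± 61.3.

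On GRCh38, with gene spans from GENCODE 29, SLC12A1 lies on chromosome 15 from 48178438 to 48304078, UMOD on chromosome 16 from 20333052 to 20356301, KCNJ1 on chromosome 11 from 128836315 to 128867373 and CLDN16 on chromosome 3 from 190322541 to 190412143. Of the proximal genes, LRP2 lies on chromosome 2 from 169127109 to 169362685, CUBN on chromosome 10 from 16823966 to 17129817, SLC34A1 on chromosome 5 from 177379235 to 177398848, SLC5A2 on chromosome 16 from 31483002 to 31490860, SLC22A6 on chromosome 11 from 62936385 to 62984983 and HNF4A on chromosome 20 from 44355700 to 44434596. All 10 are protein-coding, and the values are given per gene. Whether reads in introns were counted is not given in the sources used here.

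Among called genes with a symbol, no overlap and a mean of at least 50 in the higher segment, the largest log2 fold changes toward PT included those of LRP2, HPD, ALB, GLYAT, PLG, SLC7A7 and SLC22A8. HPD, of tyrosine breakdown, was at least 3344-fold lower in mTAL, and GLYAT, which conjugates glycine, at least 1924-fold lower (adjusted p = 0.00113 and 0.00261). ALB and PLG, best known as liver genes for albumin and plasminogen, stood at 7624 ± 4875 and 4055 ± 753 in PT with no read in mTAL, at least 3315-fold and 1763-fold lower there. The amino acid transporter gene SLC7A7 and the organic anion transporter gene SLC22A8 were at least 1513-fold and 1257-fold lower in mTAL. Toward mTAL, they included MELTF, DEGS2, ADGRL1, VAT1L, SLC5A3 and ADCY5. MELTF had 1910 ± 1478 normalized counts in mTAL and no read in PT, at least 412-fold higher (adjusted p = 0.0101), followed by DEGS2 at 191-fold, VAT1L at 123-fold and ADGRL1 at 110-fold as lower bounds. ADCY5, an adenylyl cyclase, stood at 1028 ± 202 against 6.20 ± 10.7 (log2 8.56, SE 1.59, adjusted p = 0.0249). SLC5A3 overlaps MRPS6, so its value is uncertain. Of these genes, MELTF, HPD, ALB, LRP2, GLYAT, PLG, SLC7A7 and SLC22A8 passed in each alternative setting that tested them. Of these 8, the 7 besides MELTF were not tested without a PT library. MELTF, DEGS2, ADGRL1 and VAT1L, which had no read in PT, were not tested without an mTAL library. ADCY5 missed the threshold without mTAL replicate 1 or 2 (adjusted p = 0.0839 and 0.103). SLC5A3 missed it without mTAL replicate 1 or 2 or PT replicate 1 or 3 (0.115, 0.125, 0.0797 and 0.084). ADGRL1 missed it without PT replicate 2 or 3 (0.0593 and 0.072), and VAT1L without PT replicate 1, 2 or 3 (0.0591, 0.0737 and 0.088). SLC5A3 did not pass by edgeR or DESeq2 (0.131 and 0.0986), nor did DEGS2, ADGRL1, VAT1L and ADCY5 with a replicate block (0.0575, 0.0749, 0.0815 and 0.0614).

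Over all 13251 genes tested with limma-trend, 1043 differed between the segments at an adjusted p below 0.05, 415 higher in mTAL and 628 higher in PT, with a median absolute log2 fold change of 4.64. Protein-coding genes made up 352 and 569 of these, and long noncoding RNA genes 30 and 27. No read was found in any PT library for 184 of the genes higher in mTAL, nor in any mTAL library for 193 of those higher in PT. The 3 libraries of each segment did not overlap for all 1043 and for 4058 of the 13251 tested genes (30.6%, where chance gives 10%). The count moved to 370, 422 and 923 without mTAL replicate 1, 2 and 3, and to 298, 209 and 163 without PT replicate 1, 2 and 3. The genes higher in mTAL then numbered 66, 77, 259, 145, 106 and 79, and those higher in PT 304, 345, 664, 153, 103 and 84. A gene read in 1 segment alone cannot pass the filter of 3 libraries once 1 library of that segment is left out. The counts toward the segment that lost a library are therefore lowered in part by the filter. The split between the directions rested on the scaling. With each library rescaled to the same total, 588 were higher in mTAL and 348 in PT, and with the total taken outside mitochondrial and rRNA genes, 514 and 489, as the median log2 fold change of the tested genes shifted by 0.61 and 0.26.

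Most proximal transporters were higher in PT. Of the 37 tested members, 26 were higher in PT and 1 in mTAL, or 31 and 1 adjusted over the list alone, with a median log2 fold change of -8.33 (-7.91 with genes unread in 1 segment set to their bound). SLC13A3, a dicarboxylate cotransporter gene, stood at 5338 ± 1961 in PT against 8.01 ± 13.9 in mTAL, and AQP1, the water channel of the proximal tubule and thin descending limb, at 5168 ± 1092 against 307 ± 408 (log2 -10.77 and -4.99, SE 1.30 and 0.85). The member that went the other way was SLC9A3, the sodium-proton exchanger NHE3, which both segments are known to use: 7451 ± 3368 in mTAL against 914 ± 338 in PT (log2 2.98, SE 0.41, adjusted p = 0.00945). The camera test gave an adjusted p of 3.8e-21 for the transporters, and adjusted p = 0.0549 with an estimated correlation. Of the 23 brush border and endocytosis genes, 17 were higher in PT (21 adjusted over the list alone). Their median was -6.96, with camera adjusted p = 1.4e-18 and adjusted p = 0.0152 with an estimated correlation, the 1 list of 27 to hold there. With an estimated correlation it did not hold without any 1 library or with a replicate block. ANPEP, an aminopeptidase, stood at 10580 ± 2786 in PT against 137 ± 86.5 in mTAL, and PDZK1IP1 at 6704 ± 880 against 28.7 ± 27.3. Of 10 proximal transcription factors, 6 were higher in PT, also adjusted over the list alone (median -5.09, or -4.71 with bounds), with MAF at 2082 ± 355 against 31.5 ± 28.7 and PPARA not past the threshold at 1534 ± 728 against 683 ± 378. For these, camera gave adjusted p = 1.4e-06, and adjusted p = 0.0873 with an estimated correlation. Without PT replicate 1, 2 or 3, 25 transporters were tested and 5, 4 and 2 of them were higher in PT, 7, 6 and 6 of 21 brush border genes were, and 1 of 8 transcription factors in each case. Without mTAL replicate 1 or 2, 2 and 3 of the transcription factors were. AQP1 missed the threshold without PT replicate 2 or 3 (adjusted p = 0.0589 and 0.0609) and SLC13A3 without PT replicate 3 (0.0595). By edgeR, 17 transporters, 10 brush border genes and 2 transcription factors were higher in PT, and with a replicate block 12, 11 and 1. AQP1 did not pass by edgeR (adjusted p = 0.0936).

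Genes of proximal metabolism lay toward PT in each of 4 lists by most of their members. Amino acid and one-carbon genes were higher in PT for 21 of 30 (25 adjusted over the list alone; median -5.48). Among them were GATM of creatine synthesis at 32795 ± 11721 against 637 ± 391 and ASS1 of arginine synthesis at 14960 ± 378 against 331 ± 81.6. The branched-chain and thymine breakdown gene ALDH6A1 stood at 14422 ± 7497 against 649 ± 228. Gluconeogenesis and fructose genes were higher in PT for 8 of 13 (10 adjusted over the list alone; median -5.49). PCK1, the cytosolic entry enzyme of gluconeogenesis, stood at 17231 ± 11970 against 240 ± 153 and its mitochondrial form PCK2 at 2945 ± 1015 against 29.1 ± 25.3. Xenobiotic and steroid genes were higher in PT for 12 of 21 and in mTAL for 1, GSTM3 (17 and 1 adjusted over the list alone; median -7.51, or -6.62 with bounds). UGT2B7 stood at 7282 ± 1706 against 60.9 ± 54.5, and UGT1A9 and GSTA2 at 5078 ± 1664 and 5063 ± 3341 in PT, both with reads that near-identical copies can share. Fatty acid oxidation and peroxisome genes had a negative log2 fold change in 22 of 29, while their calls split: 7 were higher in PT, including PIPOX, HAO2 and ACSM2B, and 3 in mTAL (14 and 5 adjusted over the list alone; median -1.28). Those 3 included CPT1A, which admits long-chain fatty acids to mitochondria (log2 2.30, SE 0.38), and ACADVL, the very long-chain dehydrogenase (1.84, SE 0.28). CAT and ACAA2 stood at 2760 ± 1170 and 1635 ± 618 in mTAL against 2434 ± 843 and 3127 ± 976 in PT and did not pass. Camera gave adjusted p = 4.3e-20, 6.2e-08, 1e-09 and 0.000311 for the 4 lists in this order, and adjusted p = 0.0549, 0.123, 0.0549 and 0.382 with an estimated correlation. Without PT replicate 1, 2 or 3, the genes higher in PT numbered 8, 6 and 6 (amino acid), 4, 3 and 3 (gluconeogenesis), 1, 1 and 1 of 14 tested (xenobiotic) and 5, 1 and 1 (fatty acid). Without mTAL replicate 1 or PT replicate 3, 1 fatty acid gene was higher in mTAL. CPT1A then reached adjusted p = 0.0559 and 0.0586. PCK2, UGT1A9 and UGT2B7 missed the threshold without any 1 PT library, with adjusted p up to 0.0946, 0.0803 and 0.0795, and ACADVL without PT replicate 3 (0.0624). ACSM2B missed it without any 1 PT library (up to 0.0705) and HAO2 without PT replicate 2 or 3 (0.0629 and 0.0725), while GSTA2 and PIPOX were not tested without a PT library. By edgeR, 11 amino acid, 4 gluconeogenesis, 10 xenobiotic and 6 fatty acid genes were higher in PT, and with a replicate block 16, 4, 8 and 6. UGT1A9 did not pass by edgeR (adjusted p = 0.103).

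Genes of thick ascending limb transport were higher in mTAL for 10 of 25 and in PT for 1 (15 and 1 adjusted over the list alone; median 2.13, camera adjusted p = 2.9e-08, and adjusted p = 0.211 with an estimated correlation). FXYD2, a regulator of the basolateral sodium pump, stood at 13240 ± 2210 in mTAL against 6070 ± 746 in PT (log2 1.12, SE 0.26). CASR, the calcium-sensing receptor, and WNK4, a kinase that acts on salt cotransporters, had log2 fold changes of 4.82 (SE 0.71) and 3.22 (SE 0.48). The member higher in PT was PTH1R, the parathyroid hormone receptor, which the proximal tubule is known to express (log2 -7.05, SE 1.58). PTH1R missed the threshold without PT replicate 1, 2 or 3 (adjusted p = 0.109, 0.123 and 0.146) and under rescaling to the same total (0.0678), a pseudocount of 0.5 (0.0513), no low-value filter (0.063), a replicate block (0.059) and edgeR (0.0936). CASR missed it without mTAL replicate 1 (0.0592). Secreted and identity genes were higher in mTAL for 14 of 25, among them UMOD, EGF, KNG1, MAL and ESRRB, and in PT for 1, ENOX1, (18 and 2 adjusted over the list alone; median 2.23, camera adjusted p = 7e-11, and adjusted p = 0.0845 with an estimated correlation). ENOX1 missed the threshold without mTAL replicate 1, 2 or 3 (adjusted p = 0.106, 0.163 and 0.0846), with no low-value filter (0.199), quantile normalization (0.0675), a replicate block (0.0967) and edgeR (0.0997), and was not tested without a PT library. EGF (0.0547, 0.0581 and 0.07) and KNG1 (0.0504, 0.0521 and 0.0577) missed it without mTAL replicate 1 or PT replicate 1 or 3. CYFIP2 stood at 10287 ± 1924 in mTAL against 2439 ± 631 (log2 2.10, SE 0.29), and CDH16 at 7603 ± 3530 against 1679 ± 1517 without passing (adjusted p = 0.0553). CDH16 passed in 8 of 18 alternatives: a pseudocount of 5 (0.0382), quantile normalization (0.00486), both rescalings (0.0416 and 0.0457), thinning (0.0484), array weights (0.0369), without PT replicate 1 (0.026) and DESeq2 (0.0181). Of 22 distal nephron transcription factors, 8 were higher in mTAL (10 adjusted over the list alone; median 1.78, camera adjusted p = 1.2e-06, and adjusted p = 0.0549 with an estimated correlation). POU3F3 stood at 2413 ± 152 against 755 ± 148 and PAX8 at 4488 ± 1085 against 1448 ± 370. TFCP2L1, at 1957 ± 852 against 1334 ± 765, did not pass. Without mTAL replicate 1 or 2, the genes higher in mTAL numbered 4 and 5 (transport), 5 and 9 (identity) and 4 and 4 (transcription factors). Without PT replicate 1, 2 or 3 they numbered 5, 5 and 6, then 9, 8 and 7, then 7, 7 and 4. FXYD2 passed without 1 library only when that was mTAL replicate 3, with adjusted p up to 0.263, and PAX8 missed the threshold without PT replicate 2 or 3 (0.0843 and 0.0893). By edgeR, 4 transport genes, 10 identity genes and 5 transcription factors were higher in mTAL and none of the 3 lists held a gene higher in PT. With a replicate block they numbered 6, 11 and 5. FXYD2 and PAX8 passed neither by edgeR (adjusted p = 0.14 and 0.0617) nor with the block (0.0934 and 0.0594).

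The genes of monogenic blood pressure and salt-wasting disorders were higher in mTAL for 8 of 28 tested members and in PT for 1 (10 and 2 adjusted over the list alone; median 2.04). Besides SLC12A1, KCNJ1, CASR and WNK4, which other lists also hold, SCNN1A, the alpha subunit of the epithelial sodium channel, was higher in mTAL (2670 against 292 normalized counts, log2 3.22, SE 0.38, adjusted p = 0.00555). CYP17A1, a steroid hydroxylase, was the member higher in PT (log2 -9.06, SE 1.49) and missed the threshold without PT replicate 1, 2 or 3 (adjusted p = 0.0725, 0.103 and 0.123). Camera gave adjusted p = 0.000165, and adjusted p = 0.211 with an estimated correlation. SCNN1B, SCNN1G and HSD11B2, which the collecting duct list also holds, were highest in mTAL replicate 3 (427, 2193 and 6020) and did not pass. Genes of the renin-angiotensin and natriuretic pathways were higher in PT for 6 of 19 and in mTAL for none (8 adjusted over the list alone). Their median of -3.87 rested on the filter, with 8 positive and 11 negative members, and was 0.598 over 28 members with no low-value filter. These included the peptidase genes MME at 4484 ± 1844 against 10.1 ± 17.6, ENPEP and ANPEP, besides CYP4A11 and the natriuretic peptide clearance receptor NPR3 at 3997 ± 2371 against 162 ± 101 (log2 -4.59, SE 0.57). Camera gave adjusted p = 0.00292, and adjusted p = 0.0873 with an estimated correlation. Without mTAL replicate 1, the monogenic genes higher in mTAL numbered 4, and without PT replicate 2 or 3, 5 and 5. The renin-angiotensin genes higher in PT numbered 3, 2 and 2 without PT replicate 1, 2 or 3, where MME reached adjusted p = 0.0529 and 0.0725 without replicates 2 and 3, ENPEP up to 0.088 without any 1 of them, and CYP4A11 was not tested. By edgeR, 5 monogenic genes were higher in mTAL and 4 renin-angiotensin genes in PT, and MME did not pass (adjusted p = 0.0501).

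**Figure D2:**
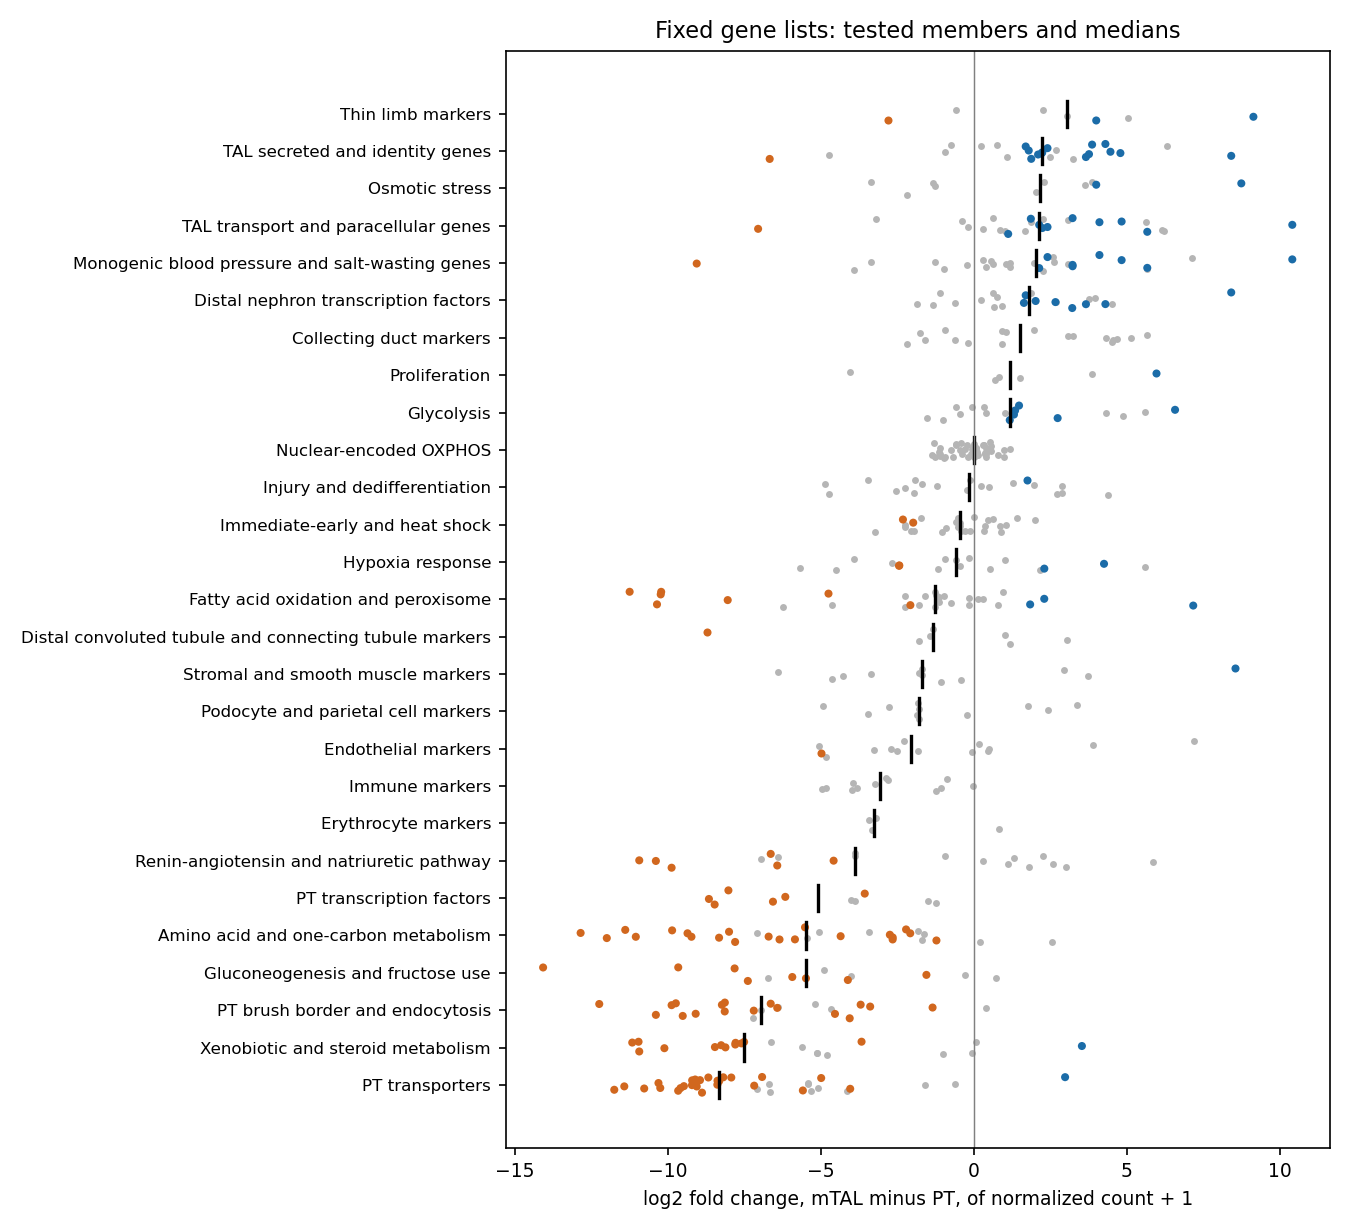
Log2 fold change (mTAL minus PT, of normalized count + 1) of each tested member of 27 gene lists, ordered by their medians (black bars); blue and orange points passed the threshold as higher in mTAL and higher in PT, and grey points did not. The PT transporters lie at a median of -8.33 and the secreted and identity genes of the thick ascending limb at 2.23.

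Glycolytic genes were higher in mTAL for 6 of 17 and in PT for none (9 and 1 adjusted over the list alone; median 1.17, camera adjusted p = 0.00073, and adjusted p = 0.0909 with an estimated correlation). The 6 were PFKL, PFKM, ALDOA, ENO1, ENO2 and PKM, with PKM at 9788 against 1584 (log2 2.73, SE 0.40) and ENO1 at 13244 ± 1949 against 4747 ± 409 (log2 1.47, SE 0.25). GAPDH had the opposite sign at 8141 ± 1495 against 16396 ± 3192 (log2 -1.01, SE 0.29, adjusted p = 0.0786) and passed with no low-value filter (0.0379), array weights (0.0393) and DESeq2 (0.00368). LDHB, at 6104 ± 976 against 8367 ± 1014, did not pass (log2 -0.46) and changed sign under rescaling to the same total. ENO1 missed the threshold without mTAL replicate 2 (adjusted p = 0.0533) or PT replicate 1, 2 or 3 (0.0693, 0.103 and 0.126). The 6 genes became 2, 1 and 4 without mTAL replicate 1, 2 and 3 and 1, 1 and 2 without PT replicate 1, 2 and 3. By edgeR 1 of the 17 was higher in mTAL and with a replicate block 2, and ENO1 did not pass by edgeR (adjusted p = 0.0548). None of 45 nuclear-encoded genes of oxidative phosphorylation passed in limma, over all genes or adjusted over the list alone, while 9 had an unadjusted p below 0.05. By edgeR 0 were called, and DESeq2 called 1 higher in mTAL and 3 higher in PT. Their median was 0.01 and their mean -0.14 (camera adjusted p = 0.622). ATP5F1B stood at 7224 ± 1380 against 5386 ± 400, ATP5F1A at 5691 ± 742 against 5388 ± 1037 and COX4I1 at 2358 ± 453 against 2518 ± 382. The sign of COX4I1 (log2 -0.10) turned under each of the 3 other scalings. Without mTAL replicate 3, 2 of the 45 were higher in PT. Rescaled to the same total, 3 were higher in mTAL and 0 in PT (median 0.62, camera adjusted p = 0.0544), with quantile normalization 2 and 0, and with the total outside mitochondrial and rRNA genes 1 and 0.

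Of 10 osmotic stress genes, 2 were higher in mTAL, both also adjusted over the list alone: AKR1B1, the aldose reductase that makes sorbitol (3176 ± 2741 against 140 ± 56.1, log2 3.99, SE 0.83), and SLC5A3, a myo-inositol transporter. These 2 became 1 without mTAL replicate 1 or PT replicate 2 and 0 without mTAL replicate 2 or PT replicate 1 or 3. The list did not pass (median 2.16, camera adjusted p = 0.131), but did without mTAL replicate 1 (adjusted p = 0.0277, and 0.259 with an estimated correlation). AQP3 stood at 1472 ± 2505 against 291 ± 108 without passing, and its direction rested on single libraries. It had 4364 in mTAL replicate 3 and 50.9 and 0 in replicates 1 and 2, so the log2 fold change was -2.20 although the mTAL mean was higher. The fold change was 0.763 without mTAL replicate 2 and 2.21 by edgeR. AKR1B1 missed the threshold without mTAL replicate 2 (adjusted p = 0.0735) or PT replicate 1, 2 or 3 (0.0684, 0.0843 and 0.103), and with no low-value filter (0.0514). Of 17 hypoxia response genes, 2 were higher in mTAL, VEGFA (log2 2.30, SE 0.33) and the glycolytic regulator PFKFB3 (4.25, SE 0.84), and 2 in PT, BNIP3 and BNIP3L (-2.45 and -2.44, SE 0.33 and 0.50). Adjusted over the list alone there were 3 and 3 (median -0.60, camera adjusted p = 0.599). PFKFB3 missed the threshold without mTAL replicate 2 or PT replicate 2 or 3 (adjusted p = 0.0585, 0.0736 and 0.0909), leaving 1 gene higher in mTAL, and BNIP3L missed it without any of these, PT replicate 1 or mTAL replicate 1 (up to 0.118), and with no low-value filter (0.0572). NDRG1 and CA12 stood at 2880 ± 1316 and 2713 ± 1227 in mTAL against 3760 ± 1037 and 1309 ± 573 in PT. NDRG1 (log2 -0.47) changed sign under quantile normalization and rescaling to the same total, and CA12 passed with array weights (adjusted p = 0.0431). Of 28 immediate-early and heat shock genes, HSPA8 and HSPD1 were higher in PT, also adjusted over the list alone (log2 -1.98 and -2.32, SE 0.24 and 0.32; camera adjusted p = 0.0634, median -0.44), and both missed the threshold under rescaling to the same total (adjusted p = 0.0662 and 0.0606). That list passed camera with no low-value filter (adjusted p = 0.00156), array weights (0.00187), without mTAL replicate 3 (0.000315) and without PT replicate 3 (0.00439), but in none of these with an estimated correlation (adjusted p = 0.336, 0.387, 0.398 and 0.494, and 0.605 in the main fit). HSP90AA1 stood at 2839 ± 686 against 4389 ± 1580. Of 20 injury and dedifferentiation genes, CD24 was higher in mTAL, also adjusted over the list alone (10597 ± 1911 against 3229 ± 993, log2 1.74, SE 0.29). SPP1 and VIM stood at 2192 ± 2491 and 1486 ± 2061 against 7200 ± 5862 and 2250 ± 2255. The injury list had a median of -0.18 where camera put it toward mTAL (adjusted p = 0.787). CD24 missed the threshold without PT replicate 2 or 3 (adjusted p = 0.0991 and 0.0998), and 2 injury genes were higher in mTAL without PT replicate 1 and 1 in each direction without mTAL replicate 3. By edgeR, CD24, PFKFB3 and BNIP3L did not pass (adjusted p = 0.0606, 0.0941 and 0.0654), nor did PFKFB3 and AKR1B1 with a replicate block (0.0687 and 0.0653). Of 6 proliferation genes, MKI67 was higher in mTAL, also adjusted over the list alone, by at least 18.1-fold at a low 83.8 normalized counts (median 1.18, camera adjusted p = 0.191). MCM5, PCNA and CCNB1 stood at 265 ± 54.8, 139 ± 62.1 and 66.8 ± 58.0 against 102 ± 54.2, 106 ± 95.2 and 44.2 ± 64.7. MKI67 missed the threshold without PT replicate 1, 2 or 3 (adjusted p = 0.135, 0.207 and 0.226), by edgeR (0.162), with quantile normalization (0.131), a pseudocount of 5 (0.0726), no low-value filter (0.28) and a replicate block (0.0975). It was not tested without an mTAL library, with a mean of at least 50 or with thinned reads.

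AQP2, the vasopressin-regulated water channel of the collecting duct, reached 25397 normalized counts in mTAL replicate 3 and at most 860 in any other library, and 18 of 22 collecting duct markers were highest in that library. None of the 18 tested passed in limma (median 1.51, camera adjusted p = 0.131; 0 at an unadjusted p below 0.05 and 0 by edgeR and DESeq2), while the list passed camera without mTAL replicate 1 or 2 or PT replicate 1 (adjusted p = 0.0165, 0.00105 and 0.0272), but in none of these with an estimated correlation (adjusted p = 0.635, 0.577 and 0.654, and 0.749 in the main fit). AQP2 stood at 8825 ± 14352 against 457 ± 432 and HSD11B2 at 2511 ± 3103 against 514 ± 188. Without mTAL replicate 3, 1 of 14 was higher in PT and camera gave adjusted p = 0.923. Of 16 stromal and smooth muscle markers, 14 were highest in mTAL replicate 1, as were 10 of 16 endothelial markers, and 14 of 20 immune markers were highest in PT replicate 1. NOTCH3 was higher in mTAL by at least 94.8-fold, the 1 of 12 tested stromal markers to pass over all genes (1 and 1 adjusted over the list alone, median -1.69, camera adjusted p = 0.627), and missed the threshold without PT replicate 1, 2 or 3 (adjusted p = 0.0665, 0.0859 and 0.0998), with no filter on low values (0.052) and with a replicate block (0.0856), and was not tested without an mTAL library. Without mTAL replicate 1, camera passed for 6 tested stromal markers (median -6.49, adjusted p = 0.00432) and for 12 endothelial markers (median -4.01, adjusted p = 0.0277), but neither held with an estimated correlation (adjusted p = 0.156 and 0.351 there, and 0.88 and 0.767 with all libraries). The medians of both lists turned positive by edgeR and DESeq2. TAGLN, ACTA2 and PECAM1 had log2 fold changes of -1.69, -4.28 and -2.30 although their mTAL means were higher. TAGLN and ACTA2 stood at 570 ± 900 and 328 ± 567 against 341 ± 406 and 302 ± 333. AQP1 was the 1 of 14 endothelial markers higher in PT (1 and 1 adjusted over the list alone, median -2.06, camera adjusted p = 0.389) and missed the threshold without PT replicate 2 or 3 (adjusted p = 0.0589 and 0.0609). PECAM1 and ESAM stood at 317 ± 481 and 726 ± 289 against 282 ± 199 and 32.9 ± 56.9. ESAM did not pass (adjusted p = 0.0662) but did in 5 of 18 alternatives, with adjusted p down to 0.024 (quantile normalization). None of 12 immune markers passed in limma (1 at an unadjusted p below 0.05, 0 by edgeR and DESeq2), while camera gave adjusted p = 0.0388 toward PT (median -3.05), and adjusted p = 0.432 with an estimated correlation. The set missed the threshold without mTAL replicate 2 or 3 or PT replicate 1 (adjusted p = 0.133, 0.0637 and 0.14). It also missed it with array weights and by fry (fry adjusted p = 0.133). CD74, HLA-DRA and LAPTM5 stood at 2266 ± 746, 275 ± 279 and 51.3 ± 53.6 against 2675 ± 2043, 1206 ± 1293 and 212 ± 263. CD74 (log2 -0.03) changed sign under the other scalings. None of 11 podocyte and parietal cell markers passed in limma (1 at an unadjusted p below 0.05, 0 by edgeR and 1 by DESeq2; median -1.81, camera adjusted p = 0.589). SYNPO and PODXL had negative log2 fold changes (-1.87 and -0.239) although their mTAL means were higher. SYNPO, PODXL and VCAM1 stood at 495 ± 699, 261 ± 284 and 58.3 ± 77.3 against 237 ± 83.2, 221 ± 91.7 and 280 ± 298. None of 4 erythrocyte markers passed in limma (0 at an unadjusted p below 0.05 and 0 by edgeR and DESeq2; median -3.26, camera adjusted p = 0.617). HBB stood at 1652 ± 1930 against 2472 ± 2721 and HBA1 and HBA2, which share reads, at 2438 ± 2935 and 3320 ± 3808 against 2582 ± 1942 and 3814 ± 3471.

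Neighbouring tubule segments showed a few differences. Of 7 thin limb markers, 2 were higher in mTAL, including AKR1B1, and CRYAB was higher in PT (3 and 1 adjusted over the list alone; median 3.04, camera adjusted p = 0.129, or 0.0398 with quantile normalization and 0.162 there with an estimated correlation). By fry the thin limb list passed (adjusted p = 0.0222). CRYAB stood at 594 ± 207 against 4078 ± 1169 (log2 -2.79, SE 0.33). Of 7 distal convoluted and connecting tubule markers, CALB1, the calcium buffer calbindin, was at least 192-fold higher in PT, also adjusted over the list alone (442 ± 185 against no read). The median of the list had no settled sign: it was -1.33 (camera adjusted p = 0.538), but 0.194 with no low-value filter, 0.542 with a mean of at least 50, 0.0248 with quantile normalization and 0.259 with array weights, and positive by edgeR and DESeq2. By fry the list passed (adjusted p = 0.00649). CALB1 was not tested without PT replicate 1, 2 or 3, where too few libraries held reads, and did not pass with a replicate block (adjusted p = 0.0803). EMX1 and CNNM2 stood at 169 ± 161 and 267 ± 81.1 in mTAL against 281 ± 92.3 and 123 ± 118 in PT. AKR1B1 missed the threshold without mTAL replicate 2 (adjusted p = 0.0735) or any 1 PT library (up to 0.103). The 2 genes higher in mTAL became 0 without mTAL replicate 2 or PT replicate 3, and 1 without mTAL replicate 1 or PT replicate 1 or 2.

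**Figure D3:**
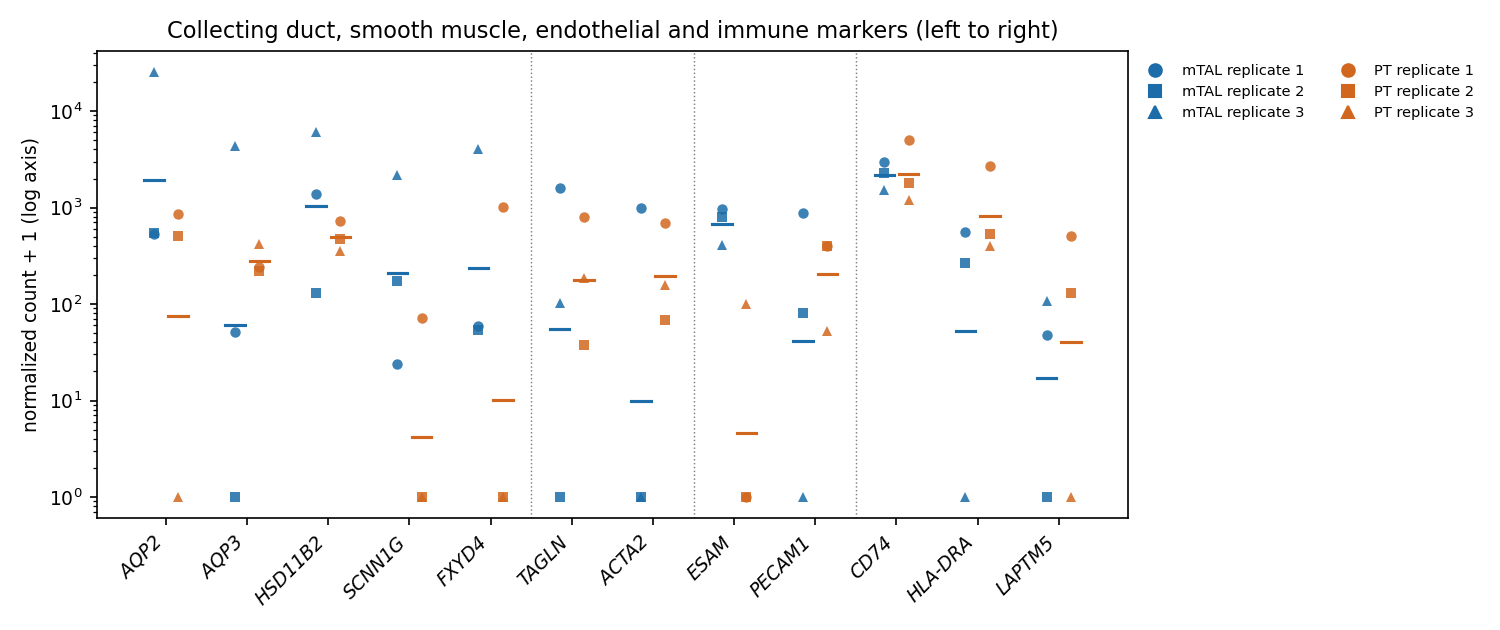
Normalized count plus 1 (log axis) of 12 markers of collecting duct, smooth muscle, endothelial and immune cells in each library, with mTAL in blue, PT in orange and a marker shape per replicate; bars are means of log2(value + 1). AQP2 reaches 25397 in mTAL replicate 3 and at most 860 in the other libraries.

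Nuclear pseudogenes of mitochondrial genes, led by MTATP6P1, MTCO1P12 and MTND2P28, held 30.0 ± 20.2% of the normalized counts in mTAL and 46.6 ± 3.03% in PT, while the 37 mitochondrial genes themselves were listed at 0 in each library, so the list of mitochondrial mRNA could not be tested. The mTAL libraries differed: the share was 17.5% (95% Wilson interval 17.46 to 17.50), 19.2% (19.14 to 19.18) and 53.2% (53.20 to 53.29) in replicates 1, 2 and 3. The difference between the segments had an exact two-sided permutation p of 0.4, and 3 libraries against 3 cannot go below 0.10. The 10 most abundant genes held 31.8 ± 18.9% in mTAL and 50.3 ± 3.08% in PT (exact p = 0.4), and rRNA genes 0.926 ± 0.475% and 0.297 ± 0.339% (exact p = 0.2). Cytosolic ribosomal protein genes held 2.65 ± 0.600% and 3.21 ± 0.853% of all counts (exact p = 0.5), or 3.94 ± 0.708% and 6.002 ± 1.276% outside mitochondrial and rRNA genes (exact p = 0.1). MALAT1 and NEAT1, long noncoding RNAs known to be abundant in nuclei, held 0.116 ± 0.0342% and 0.0204 ± 0.0133% (exact p = 0.1), or 0.184 ± 0.0914% and 0.0377 ± 0.0228% outside mitochondrial and rRNA genes (exact p = 0.1). No reference share of a nuclear library was at hand, so the nuclear source given by the labels was not tested. If the reads on mitochondrial pseudogenes came from mitochondrial RNA, that part of the RNA was not nuclear. Without mTAL replicate 3, the mTAL minus PT difference went from -16.6 to -28.3 points for the pseudogenes and from -18.5 to -29.4 for the 10 most abundant genes.

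The libraries of a segment correlated better with each other than with the other segment. Pearson correlations of log2 values across the tested genes, which are not independent replicates, ran from 0.51 to 0.68 within mTAL, from 0.60 to 0.65 within PT and from 0.31 to 0.44 between the segments. The first principal component held 42.5% of the variance and set mTAL replicate 3 apart from the rest at -318, where mTAL replicates 1 and 2 lay at -27.5 and -60.1 and the PT libraries from 105 to 155. The authors' deposited table of significant genes lists SLC12A1, UMOD, AQP1 and SLC5A12 with a mean per segment. Those means, such as 6.67 for mTAL and 3495 for PT of the lactate cotransporter SLC5A12, equal the means of the libraries. All 4 passed here, SLC5A12 missing the threshold without PT replicate 1 or 3 (adjusted p = 0.0527 and 0.0748), and the table is not independent evidence, having been made from the same libraries.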

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

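The alternatives that rescale to the total outside mitochondrial and rRNA genes or thin the reads were chosen after seeing the data. The 1043 genes past the threshold became 406 (116 higher in mTAL, 290 in PT) with no low-value filter, where more genes were tested, 380 (115 and 265) with edgeR and 1591 (695 in mTAL) with DESeq2, and 1574 (692 in mTAL) with array weights, which gave mTAL replicate 3 a weight of 0.259; for these tools and weights the cause was not tested. All 380 edgeR calls and 1018 of the DESeq2 calls were among the 1043, and no call changed sign in any alternative. Rescaling to the same total left 348 genes higher in PT, as the median shift moves each gene toward mTAL. Leaving out 1 library, which leaves fewer samples and fewer tested genes, gave 163 to 923 genes, 66 to 259 higher in mTAL and 84 to 664 higher in PT. With the replicate number as a block, 310 genes passed (101 and 209). The numbers gave no sign of pairing, as deviations of same-numbered libraries correlated at -0.009 to 0.037 and 3 of 6 libraries correlated best with their own number. The block and this check cover only the matching by these numbers, which may be permuted within a segment, so another pairing is not excluded. Of 27 lists, 14 passed camera, 15 passed fry and 1 held with an estimated correlation, the brush border list. Fry added the thin limb and the distal convoluted and connecting tubule lists and lost the immune list. Camera sets the members of a list against the other tested genes. Fry only compares them between the segments, so the counts of lists passed answer different questions. Estimating the correlation leaves camera few degrees of freedom, so p-values rose even where no correlation was found. For the distal nephron transcription factors, estimated at -0.031, the unadjusted camera p went from 3.5e-07 to 0.00497. A loss there therefore does not by itself show correlated members. With an estimated correlation, none held without 1 library or with the block, and the lists that held varied among the other alternatives. No list reversed by camera with a call in either setting, but the medians of the renin-angiotensin, distal convoluted and connecting tubule, injury, immediate-early, oxidative phosphorylation, stromal, endothelial and erythrocyte lists changed sign in some alternatives. The other alternatives changed at most 2 lists each, except leaving out mTAL replicate 1, which added the osmotic stress, collecting duct, endothelial and stromal lists. Of the 57 named genes past the threshold, 24 passed in each alternative that tested them, 43 with the block, 40 with edgeR and 52 with DESeq2; 42 of 52, 43 of 52 and 52 of 52 passed without mTAL replicate 1, 2 and 3, and 31, 26 and 21 of 47 without PT replicate 1, 2 and 3. Of 35 mTAL minus PT differences in share, recomputed without the most abundant gene or 1 library, none changed sign and each changed by less than the larger SD within a segment. That SD is wide: without mTAL replicate 3 the difference went from -16.6 to -28.3 points for mitochondrial pseudogenes, from -18.5 to -29.4 for the 10 most abundant genes and from 0.629 to 0.369 for rRNA genes, and without PT replicate 1 from -0.564 to -0.0899 for ribosomal protein genes. The spread between libraries limits what was not called: simulated 2-fold and 4-fold changes were not recovered, while at a lower simulated dispersion and the same depths 3.39% and 31.25% were. The simulation changed only 200 genes, which makes its adjusted threshold stricter than that of the data. Calls below 4-fold in the data included POU3F3 (log2 1.69) and ACADVL (log2 1.84), so the simulated recovery is no bound on what could be called. Thinning to the same total of reads outside mitochondrial and rRNA genes gave 1090 genes. It matched that total alone. Genes still detected numbered 16519, 16374 and 9900 in mTAL replicates 1 to 3. They numbered 14101, 12068 and 12631 in PT replicates 1 to 3. The lower number of genes in mTAL replicate 3 remained at an equal total of these reads, so that total does not account for it. Whether depth limited the calls was neither shown nor excluded.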

Other observations

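All tests of this part were chosen after the results were seen, except the comparison of nuclear copies with their mitochondrial genes.

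Metallothioneins, which bind zinc and copper, were higher in PT in each of the 6 tested members, with a median log2 fold change of -7.70 (4 of 6 rescaled to the same total); MT1G stood at 13600 normalized counts in PT against 59.6 in mTAL and MT2A at 2775 against 339 (log2 -9.67 and -3.49, SE 1.55 and 0.73), and their near-identical copies can share reads. HOX genes, which set the position of a cell along the body axis, lay toward mTAL with a median of 2.45 over 24 members, of which HOXD3, HOXB6 and HOXD8 passed (log2 7.35, 3.12 and 1.63, SE 1.77, 0.68 and 0.39); 7 passed with quantile normalization, 5 rescaled to the same total and 4 rescaled to the total outside mitochondrial and rRNA genes. Aldehyde dehydrogenases were higher in PT for 5 of 15 (7 with quantile normalization and 3 rescaled to the same total) and cytochromes P450 for 6 of 22. Cytosolic ribosomal protein genes were higher in PT for 34 of 81 (median -1.07), but 0 passed in limma with each library rescaled to the same total, where the median was -0.46. With the total outside mitochondrial and rRNA genes 12 were higher in PT (median -0.79), and with quantile normalization 11 (median -0.64). Translation factors were higher in PT for 9 of 67, but rescaled to the same total for 2, with 1 higher in mTAL, and with quantile normalization for 5. Collagens split 2 to mTAL and 1 to PT of 23, and 2 and 0 with quantile normalization. These are the 7 of 25 gene families, picked by symbol after seeing the data and after the values of HOX, claudin, metallothionein and apolipoprotein genes had been looked at, that passed camera (adjusted p = 0.000712 for HOX, 1.4e-06 for metallothioneins, 0.000398 for both aldehyde dehydrogenases and cytochromes P450, 6.7e-21 for ribosomal proteins, 0.000312 for translation factors and 0.0341 for collagens). None of the 25 held with an estimated correlation, the smallest adjusted p being 0.307, nor with another scaling or without 1 library, where it was 0.0749. Without PT replicate 2 or 3 the cytochromes P450 missed the threshold (adjusted p = 0.193 and 0.0531), and under rescaling to the same total the translation factors (0.0632) and collagens (0.211) did. Collagens also missed it under rescaling to the total outside mitochondrial and rRNA genes (0.0713). Apolipoproteins did not pass as a family (3 of 7 higher in PT, adjusted p = 0.0677), with APOE at 16080 ± 4440 in PT against 218 ± 171 in mTAL, nor did claudins (adjusted p = 0.139), with the paracellular sodium channel gene CLDN2 at least 540-fold higher in PT and CLDN8 at least 51.6-fold higher in mTAL. Apolipoproteins passed under quantile normalization (adjusted p = 0.0312), rescaling to the same total (0.0234) and without mTAL replicate 3 (0.0276), and claudins without PT replicate 1, 2 or 3 (0.0199, 0.00994 and 0.0275). Proteasome subunits passed without PT replicate 1 or 3 (0.0184 and 0.0275), MHC class II genes without PT replicate 2 (0.048) and potassium channels without PT replicate 3 (0.0275). Leaving out 1 library changed most of these counts, and a gene read in 1 segment alone was then not tested if that segment lost the library. No HOX gene passed without mTAL replicate 1, 2 or 3 or PT replicate 2 or 3. Metallothioneins past the threshold became 2, 0 and 0 without PT replicates 1, 2 and 3. Ribosomal protein genes became 9 and 4 without mTAL replicates 1 and 2, and 2, 3 and 1 without PT replicates 1, 2 and 3. Aldehyde dehydrogenases became 3, 1 and 1 without mTAL replicate 1 and PT replicates 2 and 3, and cytochromes P450 2 without mTAL replicate 1 or 2 and 0 without any 1 PT library. Translation factors became 4 without mTAL replicate 2 and 3, 3 and 2 without PT replicates 1, 2 and 3. No collagen passed without mTAL replicate 1 or 2 or PT replicate 2 or 3. Without mTAL replicate 3, 3 were higher in mTAL and 0 in PT, and without PT replicate 1, 1 and 0. The claudins became 0 in mTAL and 1 in PT without mTAL replicate 1 or 2, 0 and 0 without PT replicate 1 or 3, and 1 and 0 without PT replicate 2. Without mTAL replicate 2 or PT replicate 1, 2 or 3, 1 apolipoprotein passed.

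Collecting duct markers in mTAL replicate 3 form the first pattern: 18 of 22 list members were highest there, led by AQP2 at 25397, HSD11B2 at 6020 and AQP3 at 4364 normalized counts. A scaling of that library is argued against, since the list lay 5.61 above all tested genes in the log2 ratio of mTAL replicate 3 to the other mTAL libraries. A wrong label stays open: SLC12A1, UMOD, KCNJ1, CASR and EGF were at least 3.41-fold above the highest PT library, but UMOD stood at 10297 against 103634 in the lower of the other mTAL libraries, and SLC12A1 at 7115 against 26708, so a preparation mostly of another segment with some thick ascending limb is not excluded. Collecting duct cells in the preparation stay open too, since the 18 of 22 restate the pattern, and of 12 further genes, chosen after their values had been looked at, 7 were highest in that library. No biological explanation was tested, as the design gives no group within mTAL.

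Reads on nuclear copies of mitochondrial genes form the second pattern. Copies that match their mitochondrial gene at 98% or more of their bases, 4 of 388, held 97.0% of these values, and 7 copies on chromosome 1 from 629062 to 634922 held 99.7%, while the median copy matched at 73.5%. This is consistent with reads of mitochondrial RNA assigned to nuclear copies, and with the mitochondrial genes listed at 0. A difference between the segments cannot be told apart from spread between libraries, since the exact p was 0.4 and 3 libraries against 3 cannot go below 0.1.

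Thick ascending limb genes higher in the PT libraries form the third pattern. Of the 25 tested members of each of the 2 thick ascending limb lists, 4 had a negative log2 fold change: CLDN16, PTH1R, OXSR1 and RRAGD in the transport list, and ENOX1, TMEM52B, PPP1R1B and NOS1 in the identity list. PTH1R, which the proximal tubule is known to express, and ENOX1 passed the threshold. The pattern was looked at in ENOX1, CLDN16, TMEM52B and TMEM207, the last too low to be tested. TMEM52B stood at 717 ± 425 in PT against 78.6 ± 69.7 in mTAL. Carry-over of the cells sampled as mTAL was not decided: the PT level of each of these 4 was at least 69.1 times the level that a carry-over of 5.43% would bring, but the 4 genes were chosen for being higher in PT, which fixes that outcome. Cells of the cortical thick ascending limb in the PT preparations stay open, as untested, while CLDN19 lay the other way without passing (1632 ± 444 in mTAL against 66.9 ± 62.1 in PT, log2 6.22, adjusted p = 0.0589). CLDN19 passed in 8 alternatives, with adjusted p down to 0.00227 (DESeq2), and TMEM52B in 2, quantile normalization (0.0349) and without mTAL replicate 3 (0.0238).

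The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05: the split by segment gave 1043 genes in limma and was the 1 split to give as many, and the highest of the other splits gave 0.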
